A study of Homo sapiens with 3 samples.

How the data were processed

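Gene expression was measured in MCF-7 cells, an established oestrogen receptor-positive human breast cancer cell line, on Affymetrix Human Genome U133 Plus 2.0 arrays. Per the labels' protocols, cells were transfected with a lipid reagent carrying either the empty expression vector pcDNA3.1 or a human SOX2 expression construct. They were harvested 24 hours later, and amplified, biotin-labelled cRNA made from total RNA was hybridised. The labels give 1 control array and 2 SOX2 arrays, the latter named as biological replicates. The control has no replicate and no replicate number of its own.

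The deposited table holds a signal intensity for each of 54675 probe sets on each array, on a linear scale. Per the submitters' processing notes the software was GCOS 1.4. The summarisation algorithm, background correction and detection calls are not given in the sources used here. The deposited intensity values show how each array was scaled, because the mean of the probe sets without the lowest and highest 2% is 500 on each of the 3 arrays. The table was therefore taken as normalized by the authors and was not normalized again in the main analysis. Scaling of this kind fixes 1 number per array. It does not remove differences in range between arrays, or a bias that depends on signal or on the probe set. No scanner files were used here, so saturation and detection could not be read for single probe sets.

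Gene names came from the platform annotation supplied with the series. Of the 54675 probe sets, 41097 carried a single gene symbol, 1801 carried several and were not named, and 11777 were not listed and stay unnamed here. The symbols of 41043 single-symbol probe sets were matched by gene identifier to a RefSeq table of human genes, and 0 of them needed a newer symbol. The build behind the array's design is not given in the sources used here, so no genome positions are printed. The RefSeq table was used otherwise only for which genes neighbour each other.

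Signals were transformed as log2(signal + 16). The pseudocount of 16 understates the change of dim genes. The 62 control probe sets (prefix AFFX) were left out of the tests of genes and gene lists. A probe set was kept when its mean over the 3 arrays was above the median of all other probe sets, which corresponds to a signal of about 111, and 27306 were kept. Of a gene's kept single-symbol probe sets, the one with the highest mean stood for the gene, which gave 13292 genes. The SOX2 arrays were compared with the control array by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in mean signal), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This design leaves 1 residual degree of freedom per gene, to which the pooling over genes added 16.1. The spread therefore comes from the SOX2 arrays alone, and the lone control array is assumed to vary as they do. The p-values measure the spread between these arrays only. "Rose" and "fell" are used only for genes past this threshold. Beside the test, genes were counted by a fixed rule of size, at least 2-fold in both SOX2 arrays in the same direction. Values after ± are standard deviations of the 2 SOX2 arrays' differences to the control (n = 2). They hold no error for the control array. The median standard error of a gene's difference was 0.28 on the log2 scale, and the number of arrays limits the precision.

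Both differences share the control array. Their agreement was therefore set against 100 simulations of 3 unchanged arrays with the noise seen between the SOX2 arrays, and against the overlap of independent lists. The procedure was tested on simulated data of 13292 genes with 100 changed 2-fold and 100 changed 4-fold. It recovered 40.0% of the 2-fold and 70.0% of the 4-fold changes with 4 false calls. A far larger share of genes was called in the data, which loosens the adjusted threshold. These recoveries therefore do not describe the comparison made here. In 20 simulations with nothing changed the procedure called at most 1 gene and 0 gene lists. All 3 simulated arrays, the control included, carried the noise seen between the SOX2 arrays. These results therefore do not test whether the control array varies as the SOX2 arrays do.

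The design, the alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 27 lists. Camera compares a list with the other genes tested, so its direction can differ from the sign of the list's median. Its p-values with the preset correlation rest on the spread across genes and hold no error of the control array. With an estimated correlation and 1 residual degree of freedom, none of the 27 lists passed, and the lowest adjusted p was 0.855. With so few degrees of freedom that setting could hardly have called any list, so a call lost there says little about the list. Each list's median in each SOX2 array was also placed among 10000 random lists matched on mean signal in 20 bins. Both placements use the same control array. The rule named all SOX2 probe sets, the 12 genes per direction with the largest value of the smaller of the 2 differences among called genes, and up to 4 members per list with the largest such value and the same sign in both arrays. It also named CCND1, CTNNB1, MYC, ESR1, PGR, MKI67, CDKN1A and POU5F1. No probe set carried POU5F1 as its only symbol, so it is not analysed here.

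The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, eBayes without trend or robust, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets with the suffixes _x_at and _s_at (which can match several transcripts), other thresholds, and leaving out each SOX2 array. Cyclic loess normalization and a count of genes with at least 2 agreeing probe sets were added after seeing the data. The control array cannot be left out, since it is the only one of its group. The spread of the hybridisation controls, the probe sets of 1 gene and the neighbouring genes were examined as checks of the arrays. For the first of these, 18 hybridisation control probe sets were fitted together with all kept probe sets and adjusted over all of them. Figures were drawn with matplotlib 3.10.9.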

Results

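The data were 3 whole-transcriptome arrays of MCF-7 cells taken 24 hours after transfection, 1 with the empty vector and 2 with a SOX2 expression construct. SOX2 is a transcription factor of embryonic and neural stem cells. The comparison asked, per the series' design text, which transcripts differ when SOX2, studied there for its part in proliferation and tumour formation, is overexpressed. Each array gave a signal for 54675 probe sets, scaled to a trimmed mean of 500. The median signal was 139.6 on the control array, 119.9 on SOX2 replicate 1 and 125.1 on SOX2 replicate 2. The highest signal was 208841 on the control array, against 50566 and 53597 on the SOX2 arrays. Across the 13292 genes tested the SOX2 arrays correlated with each other at r = 0.971 and with the control at 0.812 and 0.806, across genes, which are not independent replicates. The number of arrays limits the precision of every value that follows.

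The targeted gene was measured by 4 probe sets, which did not move together. Probe set 214178_s_at rose from 133.7 on the control array to 43704 and 41376 on the SOX2 arrays. That is a log2 difference of 8.15 ± 0.06 or 284-fold (limma adjusted p = 8.48e-15), the largest of all genes tested. Probe set 228038_at rose 4.06-fold, from 424.8 to 1850.0 and 1701 (adjusted p = 1.57e-04 over all kept probe sets). Probe set 213721_at fell from 423.9 to 77.7 and 154.6 (log2 difference -1.80 ± 0.61, adjusted p = 0.015). Probe set 213722_at lay at 320.2, 21.2 and 38.0 and did not pass the expression filter. Which of these probe sets lie within the sequence of the construct is not given in the sources used here.

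**Figure D1:**
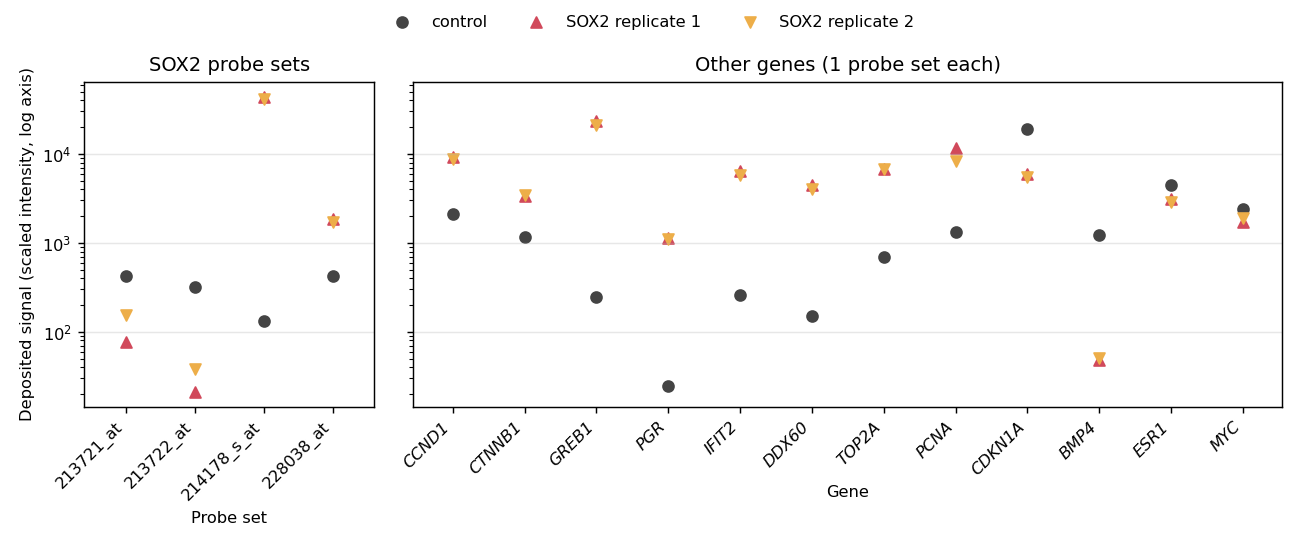
Deposited signals (log axis) of the 4 SOX2 probe sets (left) and of 12 other genes (right), 1 point per array: control as circles, SOX2 replicates 1 and 2 as triangles. Probe set 214178_s_at lies at 133.7 in the control and at 43704 and 41376 in the SOX2 arrays, while CDKN1A, BMP4 and ESR1 lie higher in the control.

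Compared with the control array, 3044 genes rose and 3356 fell in the SOX2 arrays, 48.1% of those tested. Of all genes, 2175 were at least 2-fold higher and 1715 at least 2-fold lower in both SOX2 arrays. Median centring was done over all kept probe sets, unnamed ones included, and moved the median of the genes tested from -0.15 to -0.32. With it, 1844 genes were at least 2-fold higher and 2343 at least 2-fold lower in both SOX2 arrays. By the test 2659 genes then rose and 4216 fell, so that the balance of rises and falls depends on the scaling. It also depends on the probe sets used and on the fit. Rises outnumbered falls with the mean of a gene's probe sets, with every probe set on its own, without _x_at and _s_at probe sets, and without trend. The 12 largest increases were SOX2, FANCL, GREB1, RBM48, PTGR2, UGT2B15, RCBTB1, PARD6B, STXBP3, POLR3GL, ELK3 and YEATS4. FANCL, a ubiquitin ligase of the Fanconi anaemia DNA repair pathway, went from 8.1 to 2038 and 1966 (log2 difference 6.39 ± 0.04, adjusted p = 1.15e-10; 7.78 and 4.84 with pseudocounts of 1 and 64). On the control array the signals of FANCL, RBM48, PTGR2, UGT2B15, RCBTB1, ELK3 and YEATS4, 7 of the 12, lay below the 25th percentile of all probe sets (36.7), so that the size of their differences depends on the pseudocount. UGT2B15, which glucuronidates steroids, rose by 5.68 on its main probe set and by 4.74 on the other. PARD6B, a cell polarity protein, rose by 5.57 ± 0.09, and STXBP3, a vesicle docking factor, by 5.33 ± 0.04. The ETS factor ELK3 rose by 5.15 on 1 probe set and by 1.51 on its other. For RBM48 and RCBTB1 the other kept probe sets, 3 and 1 of them, did not pass and lay between -0.09 and 0.91 and at -0.38. With a pseudocount of 1 the representative probe set of RBM48 changed, and its value was 0.58 and did not pass (adjusted p = 0.253).

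The 12 largest decreases were RASD1, BMP4, LINC01503, MAST3, POLL, PHKG2, THAP3, PLEC, TRMT2A, IFT122, SERHL2 and GDPD2. RASD1, a dexamethasone-inducible Ras-related protein, dropped from 2154 to 59.4 and 81.8 (-4.66 ± 0.27, adjusted p = 6.74e-08). BMP4, a secreted ligand of the TGF-beta family, dropped from 1236 to 48.4 and 51.0 (-4.25 ± 0.04, adjusted p = 1.35e-06). The DNA polymerase gene POLL (-3.45 ± 0.32), the phosphorylase kinase subunit PHKG2 (-3.25 ± 0.13) and the cytolinker PLEC (-3.33 ± 0.44) also fell. For RASD1, BMP4, LINC01503, MAST3, POLL, THAP3, PLEC, TRMT2A and GDPD2 both SOX2 signals lay below about 111, the signal of the filter. The size of these decreases depends on the processing. Over the alternatives RASD1 ranged from -4.93 to -4.05, BMP4 from -4.61 to -3.51, MAST3 from -4.44 to -3.25, POLL from -3.83 to -2.72 and PLEC from -3.70 to -2.60. SERHL2 fell on both of its probe sets (-3.06 and -3.91), whereas the other probe set of IFT122, which stands for the gene without _x_at and _s_at probe sets, lay at -0.19 and did not pass.

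The 2 SOX2 arrays gave the same direction for 89.2% of all genes tested, where 3 simulated unchanged arrays with a shared control gave a mean of 66.7%. Across genes the 2 differences to the control correlated at r = 0.930 (Spearman 0.913), against a simulated mean of 0.50. Their covariance was 1.31 against a simulated 0.0992, a difference of 1.21. The simulation gave a mean of 69.0 genes 2-fold higher and 68.6 lower in both, and independent lists would share 466 and 431. Any error of the single control array enters both differences alike. Between the SOX2 arrays themselves 521 genes differed by 2-fold, against 4822 and 4946 between each of them and the control.

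The control array also stood apart in transcripts that do not come from the cells. Several probe sets measure each of bioB, bioC, bioD and cre, bacterial and phage transcripts added to each hybridisation, so they are not independent checks. Fitted together with the kept probe sets, 10 of these 18 passed, 1 higher and 9 lower. Of the 27306 kept probe sets, each tested on its own, 11186 passed, a smaller share. The differences of the 18 ran from -1.79 to 0.81 with a standard deviation of 0.623, against 0.166 between the SOX2 arrays. For the genes tested these standard deviations were 1.17 and 0.446. For bioC the differences were between -1.79 and -1.12, and for bioD they ran from -0.65 to 0.81. Among 5857 genes with more than 1 kept probe set, the differences of the 2 brightest correlated at r = 0.277 (Spearman 0.277) across genes. The 3' minus 5' log2 signal of GAPDH was 0.34 on the control array and -0.03 and -0.16 on the SOX2 arrays, and that of ACTB was 1.24, 0.59 and 0.10. These values apply to every gene group described next.

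**Figure D2:**
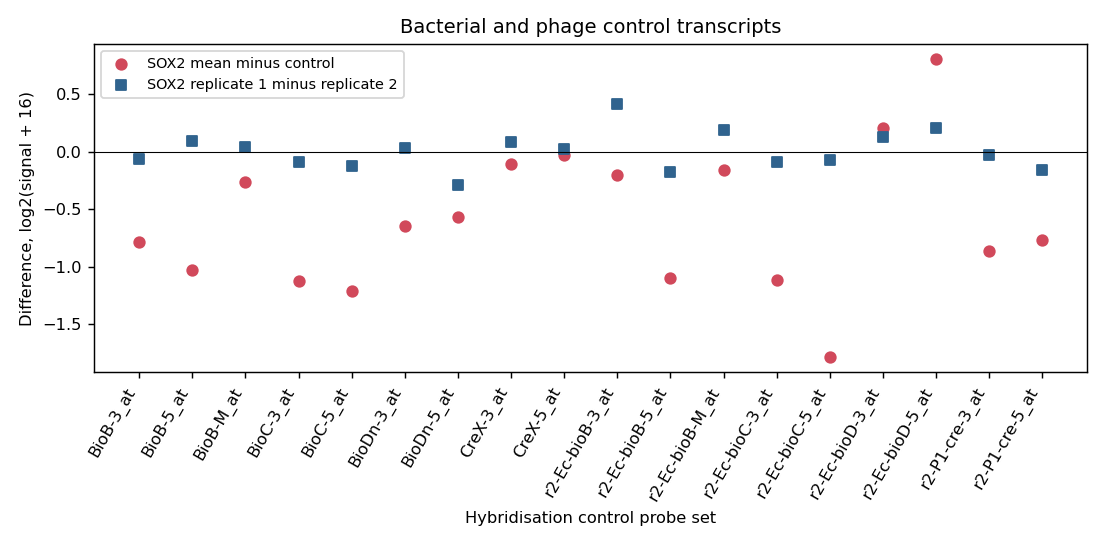
Log2 differences of the 18 hybridisation control probe sets, for the SOX2 mean minus control (circles) and for SOX2 replicate 1 minus replicate 2 (squares). The circles spread from -1.79 to 0.81, with a standard deviation of 0.623 against 0.166 for the squares.

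Genes of the interferon response were higher in the SOX2 arrays. Of 32 tested, 23 rose, 1 fell and 8 did not pass, and adjusted over the list alone 24 rose and 3 fell. DDX60 and the GTPase gene MX2, both antiviral factors, rose by 4.67 ± 0.12 (about 25.5-fold) and 4.66 ± 0.03. The control signal of MX2 was 24.9, and its difference was 5.29 and 3.60 with pseudocounts of 1 and 64. IFIT2 went from 260.6 to 6506 and 5810 (4.48 ± 0.12, adjusted p = 1.19e-10), and IFIT3 rose by 4.07 ± 0.56. Both IFIT genes also rose on a further probe set, by 2.58 and 2.53. The median of the list was 2.12, above all 10000 matched random lists in each SOX2 array (camera adjusted p = 6.35e-11). That call was lost with an estimated correlation (adjusted p = 0.855 with an estimated correlation). With 1 residual degree of freedom that setting could hardly have called any list. Of the 13 members with at least 2 kept probe sets, 10 had 2 or more past the threshold upward and none downward.

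Genes of DNA replication and of mitosis were higher as groups. Of 31 replication genes, 18 rose, 1 fell and 12 did not pass (19 and 1 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 1.81e-04, a call lost at adjusted p = 0.855 with an estimated correlation). The helicase subunit MCM4 rose 8.13-fold (3.02 ± 0.16) and its 3 other probe sets rose by 1.02 to 2.20. PCNA, the sliding clamp of DNA polymerases, rose by 2.91 ± 0.33, the licensing factor CDT1 by 2.40 ± 0.13 and the clamp loader subunit RFC3 by 2.16 ± 0.07 on its brightest probe set, while of its other 2 probe sets 1 rose and 1 lay at 0.0093. Of 32 genes of G2 and mitosis, 17 rose, 1 fell and 14 did not pass (18 and 1 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 9.97e-06, a call lost at adjusted p = 0.855 with an estimated correlation). ANLN, needed for cytokinesis, rose 14.8-fold (3.89 ± 0.10), the kinesin gene KIF23 by 3.40 ± 0.08, the checkpoint kinase gene TTK by 2.76 ± 0.03 and TOP2A, a topoisomerase of dividing cells, by 3.23 and on its other probe set by 2.53. MKI67, the proliferation antigen Ki-67, lay at 0.54 ± 0.14 on its brightest probe set and did not pass (adjusted p = 0.063), although 2 of its 3 others did, and it passed with the filter at the 75th percentile (0.0392) and with the mean of its probe sets (0.00534).

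Among regulators of the G1/S transition, 12 of 21 rose, 4 fell and 5 did not pass (12 and 5 adjusted over the list alone), and the list did not pass camera (median 0.73, adjusted p = 0.060). It did pass under 5 of 12 alternatives, over a range of 0.00366 to 0.187. CCND1, the G1 cyclin D1, rose 4.22-fold, from 2123 to 9307 and 8702 (2.08 ± 0.07, adjusted p = 1.72e-07), and by 1.09 on its other probe set. The cyclin gene CCNE2 rose by 2.83 ± 0.20, the pocket protein gene RB1 by 2.33 ± 0.02 and SKP2, which targets CDK inhibitors for degradation, by 2.21 ± 0.02. RBL2 rose by 2.56 on its brightest probe set and fell by 1.85 on the other, and the mean of both did not pass (0.35, adjusted p = 0.271). CDKN1A, the CDK inhibitor p21, fell 3.34-fold, from 19130 to 5924 and 5515 (-1.74 ± 0.07, adjusted p = 8.26e-07). MYC lay at -0.41 ± 0.09 and did not pass (adjusted p = 0.129), except with median centring (-0.58, adjusted p = 0.0339).

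Genes of Wnt signalling moved in both directions. Of 17 beta-catenin targets 7 rose, 5 fell and 5 did not pass, with the same 7 and 5 adjusted over the list alone, and camera did not call the list (median -0.10, mean 0.07, camera upward with adjusted p = 0.75). The median was 0.11 in SOX2 replicate 1 alone and 0.29 in SOX2 replicate 2 alone, so that its sign is not settled. With every probe set tested on its own the list passed upward (median 0.79, adjusted p = 0.0352; range over the alternatives 0.0352 to 0.972). The feedback inhibitor gene NKD1 rose by 2.74 ± 0.03 from a control signal of 29.3 (3.25 and 1.91 with pseudocounts of 1 and 64), while its other probe set lay at 1.31 and did not pass. The adhesion receptor gene CD44 rose by 2.23 ± 0.01, with 6 of the 8 other CD44 probe sets also up, and BMP4 belongs to this list too. Of 25 pathway components 4 rose, 6 fell and 15 did not pass, with 4 and 6 adjusted over the list alone (median -0.02, adjusted p = 0.96; -0.0038 and -0.051 in SOX2 replicates 1 and 2). CTNNB1, which encodes beta-catenin, rose 2.87-fold, from 1176 to 3383 and 3432 (1.52 ± 0.01, adjusted p = 1.49e-05), and by 1.08 on its other kept probe set. The receptor gene FZD6 rose by 2.41 ± 0.15, and AXIN1, a scaffold of the beta-catenin destruction complex, fell by 1.95 ± 0.91. APC rose by 1.74 ± 0.17, while its other probe set lay at -0.86 and did not pass, nor did the mean of both (adjusted p = 0.165).

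**Figure D3:**
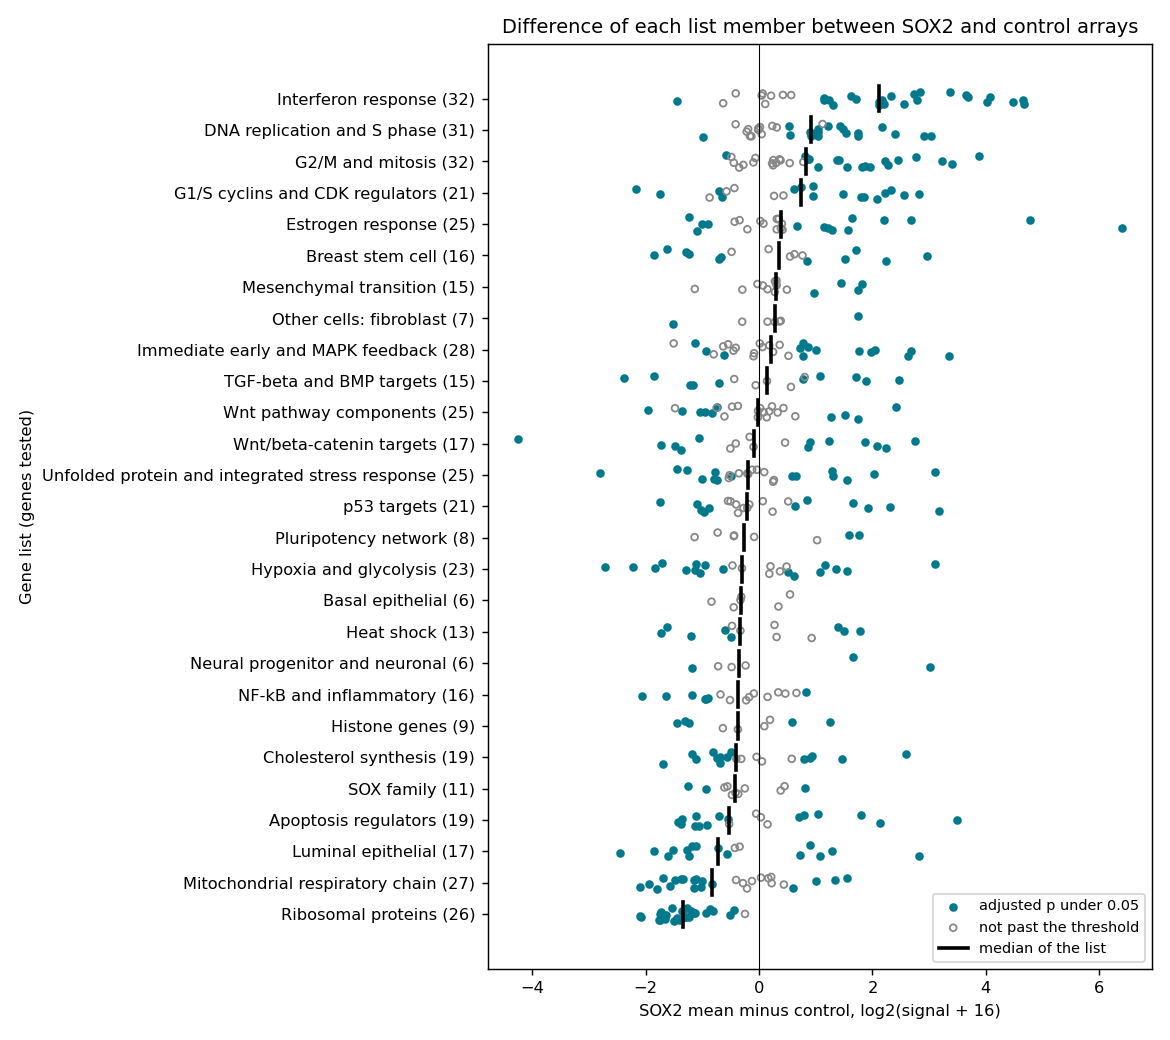
Log2 difference (SOX2 mean minus control) of every tested member of the 27 gene lists that camera tested, with filled points past an adjusted p of 0.05, open points not past it, and the list's median as a bar. The interferon list has the highest median (2.12) and the ribosomal protein list the lowest (-1.34), before any normalization of range.

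Oestrogen-responsive genes were higher as a list, with 10 of 25 up, 4 down and 11 not past the threshold, and the same 10 and 4 adjusted over the list alone (median 0.39, camera adjusted p = 0.029). This call was lost with an estimated correlation (adjusted p = 0.855 with an estimated correlation). It was also lost with a filter at the 75th percentile (adjusted p = 0.0511) and without trend (adjusted p = 0.0756), within a range of 0.00339 to 0.0756 over the alternatives. GREB1, an oestrogen receptor cofactor, went from 244.8 to 23226 and 20996 (6.40 ± 0.10, adjusted p = 4.32e-13). PGR, the progesterone receptor, rose by 4.79 ± 0.03 from a control signal of 24.8 (5.43 and 3.72 with pseudocounts of 1 and 64), while its other kept probe set lay at 0.60 and did not pass. EGR3 and the corepressor gene NRIP1 rose by 2.67 ± 0.24 and 2.20 ± 0.09. ESR1, the oestrogen receptor itself, fell by 0.57 ± 0.07 (adjusted p = 0.026), a call that ended with quantile normalization (adjusted p = 0.0582), without trend (0.119) and with the mean of its probe sets (0.67), over a range of 0.00603 to 0.67.

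Markers of luminal cells went both ways, with 5 of 17 up, 10 down and 2 not past the threshold (5 and 11 adjusted over the list alone; camera adjusted p = 0.17). The adhesion molecule gene EPCAM rose by 2.82 ± 0.01, and the keratins KRT18 (-2.44 ± 0.22), KRT8 (-1.85 ± 0.08) and KRT19 (-1.52 ± 0.16) fell. After quantile normalization KRT8 and KRT19 lay at -0.26 and -0.08 and did not pass, and KRT18 passed at -0.60 (adjusted p = 0.0189). After cyclic loess all 3 passed, at -1.46 (KRT18), -0.91 (KRT8) and -0.63 (KRT19). None of 6 basal markers passed either way in the main analysis (0 and 0 adjusted over the list alone; median -0.32, adjusted p = 0.88; -0.34 and -0.019 in SOX2 replicates 1 and 2), among them ITGA6 at 0.55, CDH3 at -0.45, LAMB3 at -0.33 and TRIM29 at -0.84. With median centring TRIM29 (adjusted p = 0.0315) and CDH3 (0.0267) did pass, as did TRIM29 without _x_at and _s_at probe sets (0.038) and ITGA6 with the mean of its probe sets (0.046). Of 15 mesenchymal genes 4 rose, none fell and 11 did not pass (4 and 0 adjusted over the list alone; adjusted p = 0.23), with ITGAV up by 1.81 ± 0.03, COL3A1 by 1.75 ± 0.21 and TGFBI by 1.45 ± 0.09, and TGFB2 at -1.13. TGFB2 passed with median centring (adjusted p = 0.0335) and without trend (0.0214). Tested with every probe set on its own, the mesenchymal list (adjusted p = 0.0219, range 0.0219 to 0.764) and the breast stem cell list (0.0189, range 0.0189 to 0.901) passed upward. Of 16 breast stem cell genes 5 rose and 6 fell, as over the list alone (adjusted p = 0.88), with the Notch target HEY2 up by 2.97 ± 0.41 from a control signal of 27.6 (3.51 and 2.09 with pseudocounts of 1 and 64), ID4 by 1.71 ± 0.07, and the receptor gene NOTCH3 lower (-1.62 ± 0.05). Of 7 fibroblast markers COL3A1 rose and COL5A1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.88), while DCN lay at 0.38 and COL6A3 at -0.30. The 2 other COL5A1 probe sets did not pass (-0.70 and 0.20), nor did the mean of all 3 (-0.67, adjusted p = 0.164). Only 3 blood and endothelial markers passed the filter, too few for camera, and none passed the test in either adjustment (HBB at 0.58).

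Ribosomal protein genes were lower. Of 26 tested, 25 fell, none rose and 1 did not pass, with the same 25 adjusted over the list alone, and the median was -1.34 (camera adjusted p = 5.00e-12). That call was lost with an estimated correlation (adjusted p = 0.855 with an estimated correlation) and with quantile normalization (0.835). RPL32 (-2.09 ± 0.04), RPS15 (-2.08 ± 0.04), RPL3 (-1.76 ± 0.01) and RPS6 (-1.72 ± 0.01) fell. These are among the brightest genes, and the 100 genes brightest on the control array fell without exception, with a median of -1.45. The control signal that picked these genes is itself part of the difference, so the choice favours lower values. In the tenth of genes with the highest mean signal the median difference was -0.41. After quantile normalization 26 of these 100 genes were lower, 10 were higher and their median was -0.16, and after cyclic loess 74 were lower, 1 was higher and the median was -0.60. Against 10000 random lists matched on mean signal, whose medians were -0.52 and -0.60 in the 2 SOX2 arrays, the ribosomal list lay at percentile 0 in both. The matching used 20 bins, within which the ribosomal list could still be brighter than the genes drawn. After quantile normalization the list's median was -0.09 (camera adjusted p = 0.835, range over the alternatives 2.08e-12 to 0.835), RPS6 no longer passed (-0.19), and RPL32 (-0.70), RPS15 (-0.82) and RPL3 (-0.94) passed with smaller differences. After cyclic loess the list passed with a median of -0.53 (camera adjusted p = 0.00108), and RPS6 lay at -0.81 (adjusted p = 4.07e-04). Of 27 respiratory chain genes 14 fell, 4 rose and 9 did not pass, as over the list alone (median -0.83, camera adjusted p = 0.022). That call was lost with quantile normalization (adjusted p = 0.529), cyclic loess (0.555), without trend (0.102) and with an estimated correlation (adjusted p = 0.855 with an estimated correlation); with the preset correlation the alternatives ranged from 0.00445 to 0.555. UQCRC1 (-2.11 ± 0.02), ATP5F1B (-1.95 ± 0.05), NDUFA8 (-1.80 ± 0.19) and ATP5F1A (-1.69 ± 0.22) fell.

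Metabolic and stress lists held rises and falls and did not pass camera. Of 23 hypoxia and glycolysis genes 7 rose and 10 fell (adjusted p = 0.75), among them the lipase inhibitor gene ANGPTL4 at -2.72 ± 0.09 and ANKRD37 at -2.22 ± 0.001, both down, and VEGFA, the angiogenic growth factor, up by 3.11 ± 0.25. The other ANGPTL4 probe set lay at 0.27 and did not pass. Of the 3 other VEGFA probe sets 1 rose and 1 fell. ALDOA fell by 1.83 ± 0.08, but of its other 2 probe sets 1 fell and 1 rose, by 2.40, and it did not pass after quantile normalization (-0.27, adjusted p = 0.147) or with the mean of its probe sets (-0.38, adjusted p = 0.0745). Of 19 cholesterol synthesis genes 5 rose and 9 fell (adjusted p = 0.75), with LSS lower (-1.69 ± 0.11), MVD up by 2.59 ± 1.01 from a control signal of 33.5 (3.03 and 1.85 with pseudocounts of 1 and 64), MSMO1 up by 1.46 ± 0.34, and NSDHL at -1.11 on 1 probe set and 1.73 on the other, both past the threshold. The 2 other LSS probe sets did not pass (-1.10 and -0.59). Of 13 heat shock genes 3 rose and 5 fell (adjusted p = 0.88), with HSPE1 up by 1.78 ± 0.05, HSPH1 up 2.82-fold, and HSPB1 (-1.73 ± 0.10) and HSP90AB1 (-1.61 ± 0.14) lower. HSPB1 no longer passed after quantile normalization, and both other HSP90AB1 probe sets rose. The 2 other HSPH1 probe sets did not pass (-0.26 and 0.19). Of 25 genes of the unfolded protein and integrated stress responses 7 rose and 8 fell (adjusted p = 0.88), with the chaperone gene HSPA5 up by 1.56 ± 0.06, PSAT1 up by 2.04 ± 0.14 and DDIT3 lower (-2.80 ± 1.09). The other HSPA5 probe set lay at 0.023 and did not pass. Adjusted over the list alone the counts were 7 and 10 for hypoxia, 5 and 9 for cholesterol, 3 and 6 for heat shock and 7 and 10 for the stress responses.

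Of 21 p53 targets 6 rose and 5 fell (6 and 6 adjusted over the list alone; median -0.21, mean 0.15, camera upward with adjusted p = 0.88). PMAIP1, a pro-apoptotic BH3 protein, rose by 3.17 ± 0.22, MDM2 by 2.32 ± 0.34 and PPM1D by 1.91 ± 0.06. CDKN1A, also on this list, fell (-1.74 ± 0.07). Of the 4 other MDM2 probe sets 2 rose and 2 did not pass, the lowest at -0.83, and the other PPM1D probe set lay at 0.015 and did not pass. Of 19 apoptosis regulators 6 rose and 9 fell in both adjustments, the second being adjusted over the list alone (adjusted p = 0.88). XIAP, a caspase inhibitor, rose by 3.48 ± 0.21 with all 5 other probe sets up, APAF1 by 2.14 ± 0.04 and CASP8 by 1.79 ± 0.27, and BAK1 fell by 1.44 ± 0.11, while the other APAF1 probe set lay at 0.40 and did not pass. Of 16 NF-kB and inflammatory genes 1 rose and 6 fell, as over the list alone (adjusted p = 0.51), with TRAF1 (-1.65 ± 0.13), IL1B (-1.18 ± 0.18), NFKB1 (-0.96 ± 0.10) and TNF (-2.06 ± 1.44) lower. The other IL1B probe set lay at -0.81 and did not pass. The other TRAF1 probe set lay at -0.09, and the mean of both did not pass (-0.87, adjusted p = 0.113). TNF did not pass under 6 of the 10 alternatives that measured it, over a range of adjusted p from 0.00866 to 0.105. Of 28 immediate early and MAPK feedback genes 11 rose and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.23), with KLF10 up by 3.36 ± 0.10, SPRY4 by 2.63 ± 0.36 from a control signal of 36.7 (3.05 and 1.90 with pseudocounts of 1 and 64) and DUSP6 by 1.98 ± 0.18.

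Of 15 TGF-beta and BMP targets 5 rose and 5 fell (5 and 6 adjusted over the list alone; adjusted p = 0.88), with TGFBR1 up by 2.46 ± 0.09, ID2 by 1.88 ± 0.08 and PMEPA1 lower (-2.38 ± 0.10), with 1 of its 2 other probe sets down and 1 at -0.97 that did not pass. Without _x_at and _s_at probe sets TGFBR1 lay at 0.20 and did not pass (adjusted p = 0.705). Of 9 histone genes 2 rose and 3 fell, as over the list alone (adjusted p = 0.75), with H2AZ1 up by 1.26 ± 0.04 and H1-2 (-1.45 ± 0.08), H2BC5 (-1.30 ± 0.12) and H2BC21 (-1.23 ± 0.02) lower. The other H2BC5 probe set lay at 0.62, and the mean of both did not pass (-0.34, adjusted p = 0.393). Of 8 pluripotency genes KLF4 (1.76 ± 0.10) and NODAL (1.59 ± 0.04) rose and 6 did not pass, as over the list alone, among them DPPA4 at -1.14 and GDF3 at 1.02 (median -0.26, mean 0.19, camera upward with adjusted p = 0.88). The other KLF4 probe set lay at 0.010 and did not pass, and the list's median was -0.33 and -0.081 in SOX2 replicates 1 and 2. NODAL did not pass with no expression filter (adjusted p = 0.0584), and DPPA4 passed with median centring (0.0349) and without trend (0.0205). Of 11 other SOX genes SOX12 rose by 0.82 ± 0.56 and SOX9 (-1.25 ± 0.07) and SOX15 (-0.94 ± 0.17) fell, SOX6 lay at -0.56, and adjusted over the list alone 0 rose and 1 fell (camera adjusted p = 0.88). The other SOX9 probe set lay at -0.35 and did not pass. SOX12 did not pass under 8 of 12 alternatives, over a range of adjusted p from 0.00525 to 0.976, and SOX15 did not pass with no expression filter (0.0796). Of 6 neural genes NES, an intermediate filament of neural progenitors, rose by 1.67 ± 0.09, TUBB3 fell by 1.19 ± 0.01 (its other probe set lay at -0.33 and did not pass), MAP2 lay at -0.72, and MSI2 rose by 3.01 ± 0.26 while 3 of its 8 other probe sets rose and 2 fell. MSI2 did not pass with the mean of its probe sets (adjusted p = 0.0552) or without _x_at and _s_at probe sets (0.669), and MAP2 passed with median centring (0.0404). The neural counts were 2 and 1 both over all genes and adjusted over the list alone (median -0.36, mean 0.34, camera upward with adjusted p = 0.94; medians -0.46 and -0.21 in SOX2 replicates 1 and 2).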

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

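The tests of the hybridisation controls, of the range of the arrays and of the 2 brightest probe sets of each gene were chosen after their results had been seen, as were cyclic loess, the count of agreeing probe sets and the use of lists matched on mean signal to weigh compression. The array carries control probe sets, left out of the comparisons, named for the interferon-stimulated factor HUMISGF3A. They were higher in the SOX2 arrays than in the control. The 3' probe set went from 2601 to 18156 and 15538, a ratio of 6.48, the 5' probe set from 715.3 to 3371 and 3575, a ratio of 4.86, and the probe set MB from 3277 to 8880.0 and 6740.2, a ratio of 2.38. Of 4320 kept probe sets with no single gene name, 590 were past the threshold and at least 2-fold higher in both SOX2 arrays and 455 were lower.

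The first pattern is that 48.1% of the genes tested were called. A difference in the range of the arrays is argued against as the whole cause, because 6107 genes were called after quantile normalization against 6400 before it, with 5803 shared in the same direction. A difference between the hybridisations stays open. The spike transcripts, whose values raised it, differed from the control with a standard deviation 3.76 times that between the SOX2 arrays, and 10 of their 18 probe sets were called, so how much of the pattern it covers is not known. Behaviour of single probe sets stays open too, since the 2 brightest probe sets of a gene correlated at 0.277 where the noise between the SOX2 arrays would allow 0.905, but transcript variants would lower this value as well. SOX2 itself, the transfection of the single control and its hybridisation cannot be told apart in this design, which gives the control 1 array, and the fit's spread holds no control error.

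The second pattern is the rise of interferon response genes. If single probe sets drove it, the other probe sets of the same genes would not follow more often than elsewhere. Of the other probe sets of called members, 12 of 14, or 85.7%, were called in the same direction, against 31.1% for all called genes. The exact binomial 95% interval was 57.2 to 98.2, and it treats probe sets of the same gene as independent. The comparison with all called genes was not matched on the size of the difference. It therefore does not decide how far single probe sets contribute, although most of these other probe sets did follow. A trend shared by neighbouring genes is argued against. The median was 1.80 after the median of 20 neighbours was taken off, against 2.12 before. The HUMISGF3A control probe sets moved the same way. It also stays open whether SOX2, the plasmid preparation or transfection of the single control culture, or the cultures themselves made the difference. None of these causes was tested.

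The third pattern is the fall of ribosomal protein genes. Whether compression of bright signals on the SOX2 arrays accounts for it is not decided by these values. Among 10000 random lists matched in 50 bins on the control array's signal, the median was -1.14 and the list lay at percentile 3.38. That signal is itself part of the difference. Among lists matched on mean signal in 20 bins the medians were -0.52 and -0.60 and the list lay at percentile 0 in both SOX2 arrays. Within bins of this width the list could still be brighter than its matched genes, which was not examined. Quantile normalization, which equalises the range, left a median of -0.09 and ended the call (camera adjusted p = 0.835), whereas cyclic loess, which takes off a trend with signal, left -0.53 and kept it (camera adjusted p = 0.00108). Before either normalization the call was lost with an estimated correlation (adjusted p = 0.855 with an estimated correlation). With 1 residual degree of freedom that setting could hardly have called any list, so it does not help to decide. Of 16 other probe sets of the called members 6, or 37.5% (15.2 to 64.6), fell too and 3 rose, which is too few to decide whether single probe sets matter. A lower level of ribosomal protein transcripts with SOX2 therefore stays open and untested here.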

How the results depend on the processing

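Cyclic loess and the agreeing probe sets were chosen after seeing the data, and the other alternatives before the data were examined. No paired analysis was possible because the control group has 1 array and carries no replicate number. Without either SOX2 array no degree of freedom is left for a test, and the size rule then counted 2461 to 2519 genes higher and 2361 to 2427 lower. The SOX2 probe sets ranged from 8.11 to 8.19 (214178_s_at), 1.96 to 2.08 (228038_at), -2.23 to -1.37 (213721_at) and -3.18 to -2.64 (213722_at). Detection calls are not given, so signal over background could not be read, and the size of changes from dim signals depends on the pseudocount.

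Counts of called genes stayed within 1.5 times of 3044 higher and 3356 lower under 11 alternatives with a gene as the unit and at an adjusted p under 0.1. The number of genes tested differed, from 8162 with the filter at the 75th percentile to 19775 with no filter. The share called was therefore not stable. It was higher with the stricter filter and lower with no filter than in the main analysis. Counting every kept probe set gave 6068 higher and 5118 lower (27306 tested), and requiring 2 agreeing probe sets, possible for 5857 genes only, gave 826 and 456, where the main analysis had called 1616 and 1486 of those genes. More of these 5857 genes had probe sets called in both directions than had agreeing falls. The size rule of 2175 and 1715 gave 4848 and 3112 with every probe set, 3012 lower with no filter (more genes counted), 3513 lower at 1.5-fold, and 1169 and 358 at 3-fold. Median centring, done over all kept probe sets, moved the median of the genes tested from -0.15 to -0.32. The main median already lies below 0, so directions of small changes are relative to it.

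The 4 lists higher and 2 lower past camera's threshold became 0 and 0 with an estimated correlation, 0 lower with quantile normalization, 1 lower with cyclic loess, 1 lower without trend and 8 higher with every probe set; the cause was not tested beyond the range of the arrays. The estimated correlation could hardly have called any list with 1 residual degree of freedom. The interferon, replication and mitosis lists passed in the same direction in all 12 other alternatives (medians 1.80 to 2.19, 0.75 to 1.04 and 0.66 to 1.48). Probe set 214178_s_at took values of 8.81 (quantile), 7.98 (median centring), 8.30 and 7.75 (pseudocounts 1 and 64) and 8.37 (loess). Probe set 228038_at took 1.90, 1.85 and 1.91 (quantile, median centring, pseudocount 64), and 213722_at -3.45 and -2.04 (pseudocounts 1 and 64).

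Camera's direction reversed only for lists that it did not call, with these medians; the cause was not tested. With quantile normalization they were p53 -0.37, heat shock 0.35 and hypoxia 0.26. With no filter they were pluripotency -0.44 and heat shock -0.33, and at the 75th percentile Wnt components 0.019 and breast stem cell -0.48. With the mean of probe sets they were p53 -0.26, apoptosis -0.27, Wnt components -0.018, neural -0.24, luminal -0.062 and heat shock 0.27, and with every probe set apoptosis 0.094, stress responses 0.057 and heat shock 0.31. Without _x_at and _s_at they were p53 -0.15, neural -0.14, stress responses 0.027, heat shock 0.51, hypoxia 0.065, cholesterol 0.036 and TGF-beta 0.041. With loess they were stress responses -0.061, heat shock 0.22 and hypoxia -0.23. Of the named genes, the mean of probe sets reversed HSP90AB1 (0.13), NSDHL (0.31) and HBB (-0.21), and leaving out _x_at and _s_at reversed RBM48 (-0.091), MSI2 (-0.14), MAP2 (0.22), NSDHL (1.73) and HBB (-0.57), since other probe sets then stand for these genes. Of the named genes' other values, 1404 kept direction and side of the threshold, 36 lost the call and 12 gained it.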

Other observations

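The genes named here, and the tests of neighbouring genes and of groups by signal in this section, were chosen after the values were seen. Some genes were measured by several probe sets that all gave the same call. Among 2445 genes with at least 3 kept probe sets, all of them rose for 92 genes and all fell for 53. The replication initiation factor MCM10 had the highest median among the former (4.74 over 3 probe sets, from 1.04 to 5.74), followed by the serine protease PRSS23 (3.78). The Notch ligand JAG1 rose on 3 of 3 probe sets (median 3.43), the chromatin ATPase ATAD2 on 4 of 4 (3.24), PHLDA1 on 6 of 6 (2.11) and PAIP1 on 5 of 5 (2.36). All kept probe sets also rose for OAS2 (median 3.37), the RNA-activated kinase EIF2AK2 (2.55), the death ligand TNFSF10 (2.15), SAMHD1 on 5 of 5 (2.08) and IFIH1 (1.97).

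Among the genes with all probe sets lower, GIT2 (-2.07), MLLT6 (-1.97), GAPDH (-1.92), the tubulin cofactor TBCB (-1.85), GRHPR (-1.77) and the ubiquitin ligase STUB1 (-1.74) had the lowest medians. ACTB fell on 3 of 3 (-1.47), as did the splicing factor RBM10 (-1.67), the calcium-binding protein ANXA2 (-1.45) and GADD45B (-1.40). GAPDH and ACTB are used as reference genes in many assays. After quantile normalization the brightest probe sets of GAPDH (-0.24, adjusted p = 0.242), ACTB (-0.011, 0.953) and STUB1 (-0.26, 0.219) did not pass, whereas that of RBM10 did (-1.69, adjusted p = 5.74e-04). After cyclic loess GAPDH (-0.96, adjusted p = 1.23e-04), ACTB (-0.76, 4.90e-04) and RBM10 (-1.67, 2.22e-05) passed and STUB1 did not (-0.046, 0.837).

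Neighbouring genes on a chromosome had differences to the control that were more alike than in shuffles, and whether this comes from the base composition of their probe sets was not tested. Across 13258 genes, a gene's difference correlated with the median difference of its 20 nearest measured neighbours at r = 0.251, against 0.0106 for the difference between the SOX2 arrays and at most 0.0109 in 20 shuffles. In the tenth of genes with the highest mean signal the median difference was -0.41, with 347 genes up and 624 down.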
